A study of Mus musculus with 11 samples.

How the data were processed

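RNA was measured in pancreatic islets from mice of mixed background. Per the labels' protocols, the pancreas was digested with collagenase, islets were separated on a density gradient, and polyadenylated RNA was sequenced on an Illumina platform after a stranded mRNA library preparation with depletion of ribosomal RNA. The labels divide 11 libraries into 7 wild type and 4 Hnf1a flox, the latter homozygous and from mice in which Ngn3-cre, a recombinase active in endocrine progenitors, acts on a floxed Hnf1a gene. By the labels, 5 wild-type libraries came from females and 2 from males, against 3 females and 1 male for Hnf1a flox. All wild-type mice had normal glycaemia and all Hnf1a flox mice were hyperglycaemic, so genotype and glycaemia have the same split. The labels give neither the floxed exon nor whether wild-type mice carried the recombinase. They do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries.

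The authors deposited length-normalised transcript abundances scaled to a fixed library total (TPM) for 41740 Ensembl genes in 11 libraries, and each library summed to 1000000. The genome build was GRCm38, per the submitters' processing notes, which also name edgeR and DESeq2 1.28.1 without saying what each was used for. The aligner and the read counter are not given in the sources used here. TPM divides by gene length and by the library's total, so a cell type that takes a large share of one library lowers all other genes in it. The deposited values are TPM, so the main test was not a count-based one.

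Gene names and coordinates came from GENCODE mouse release M21, which is built on GRCm38. It held 41682 of the gene identifiers (99.9%). TPM itself keeps no depth, but multiplying it by the exon length of this release and dividing by the smallest step in each library gave whole reads, within 0.02 of a read, for 98.1% of 72621 values below 200 reads, where chance would give 4%. On that scale the libraries held 37592648 to 55945531 reads, with a median of 46968742 for wild type and 45436502 for Hnf1a flox. These reads describe depth and served in 1 alternative fit, by limma's voom, added after the data were seen.

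Genes with at least 1 TPM in at least 4 libraries (15011 genes) were analysed as log2(TPM + 1), so fold changes are on that scale and understate the change of genes with low values. Hnf1a flox was compared with wild type by limma 3.58.1 in R 4.3.3, with sex as labelled in the model and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had been written for TPM with a count test as a fallback that was not needed. The effect of genotype by sex was an interaction term in the same kind of fit. Hormone shares were compared by an exact permutation test over all 330 splits of the libraries, two-sided, whose smallest possible p is 0.00303. The 29 gene lists (681 entries, 3 of which matched no gene in the file: 2 acinar and 1 erythroid) were tested by limma's camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation. A list score is the mean log2(TPM + 1) of its genes. For symbols listed more than once, the copy with the higher mean TPM was used. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for the rest.

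The comparisons, the gene lists and the rule for named genes were set before the data were examined. The rule takes Hnf1a, the 5 islet hormones, up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold with at least 5 TPM in a group and no overlap between groups, and from each list up to 4 members past the threshold (2 for lists of other cell types), or the 2 most expressed members where fewer than 2 pass. Unnamed gene models, Y-linked genes, Xist and antigen receptor segments were left out. Other genes named are said to be outside the rule. Lists of pan-endocrine (8 genes), Y-linked (4 genes) and intestinal epithelium genes (12 genes) were added after the data were seen.

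The limma fit was tested on simulated data for the comparison of Hnf1a flox with wild type over 15011 genes, of which 200 were changed. It recovered 0% of the changed genes at a log2 change of 1, 26.5% at 2 and 94.5% at 4, with 0, 3 and 9 false calls. Alternatives covered the pseudocount, the filter on low values, scaling, the sex term, females only with and without wild type 5, the replicate number as a block, the variance model, library weights, scores of other cells as covariates, and leaving libraries out. DESeq2 was not run.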

Results

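Gene expression was measured in islets of 7 wild-type and 4 Hnf1a flox libraries to ask what loss of Hnf1a in the endocrine pancreas changes. Hnf1a encodes a transcription factor whose mutation causes a monogenic form of diabetes. The libraries held 37592648 to 55945531 reads.

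The libraries differed in the cells they held. Prss2, a trypsinogen gene of acinar cells, ranged from 888 to 66427 TPM over the wild-type libraries. The acinar score was highest in wild type 5 (11.22) and Hnf1a flox 3 (11.18). Leukocyte genes also varied, with a score of 6.42 ± 1.62 in wild type (SD, n = 7) and 6.78 ± 1.15 in Hnf1a flox (SD, n = 4). The pan-endocrine score, from 8 secretory granule and endocrine genes, was 9.03 ± 0.67 in wild type and 7.62 ± 1.47 in Hnf1a flox (exact permutation p = 0.0606). Hnf1a flox 2 (5.98) and Hnf1a flox 3 (6.80) lay below all wild-type libraries on this score, and Hnf1a flox 1 (8.76) and Hnf1a flox 4 (8.96) lay within their range. Intestinal epithelium genes were expressed in wild type 2 and wild type 4, with Fabp2, an enterocyte fatty acid-binding protein gene, at 425 and 3857 TPM. Their intestinal scores were 5.49 and 8.59, against 0.02 to 0.23 in the other 9 libraries. Wild type 5 was labelled female but expressed the Y-linked gene Ddx3y at 21.3 TPM. The first principal component held 62.7% of the variance and set wild type 4, wild type 5 and Hnf1a flox 3 apart from the other 8 libraries.

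**Figure D1:**
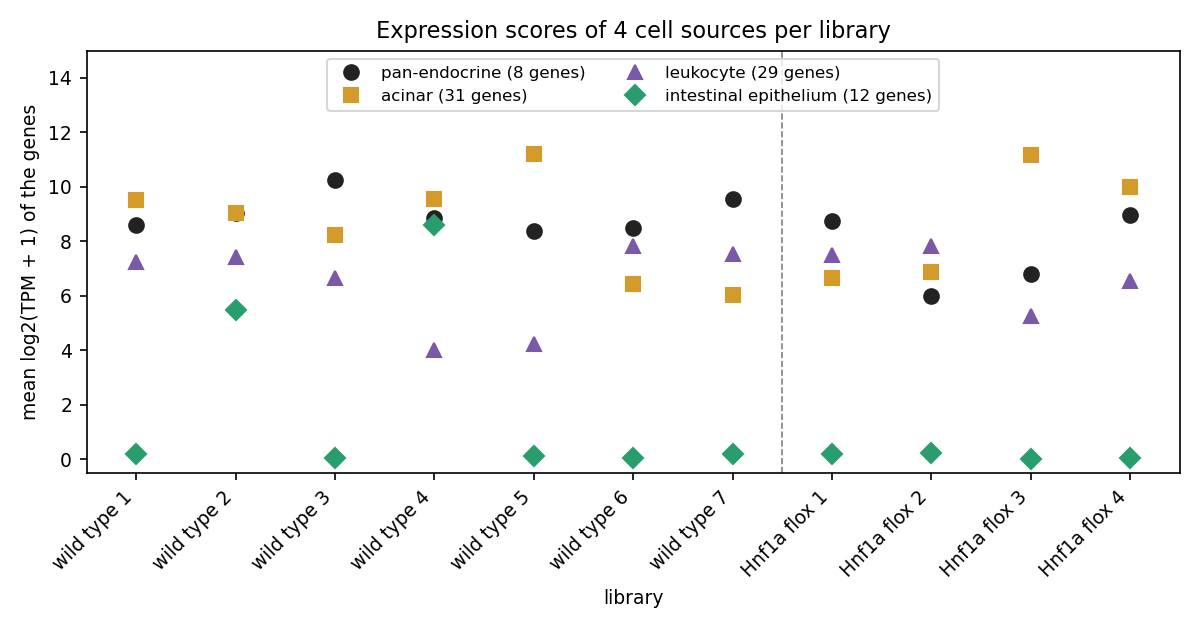
Mean log2(TPM + 1) of pan-endocrine, acinar, leukocyte and intestinal epithelium genes (y axis) in each of the 11 libraries (x axis), 1 point per library and gene group. Intestinal scores stand at 5.49 in wild type 2 and 8.59 in wild type 4 and at or below 0.23 in the other 9 libraries.

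Hnf1a itself (ENSMUSG00000029556, chromosome 5, 114948980 to 114971094, GRCm38) was at 3.52 ± 2.84 TPM in wild type (SD, n = 7) and 0.967 ± 0.661 TPM in Hnf1a flox (SD, n = 4). The wild-type libraries, in the order of their numbers, held 1.79, 1.62, 6.00, 8.74, 1.22, 1.78 and 3.52 TPM. The Hnf1a flox libraries held 0.93, 0.06, 1.33 and 1.55 TPM, of which 2 exceeded wild type 5. The log2 change was -1.08 ± 0.45 (SE), with an exact permutation p of 0.0364 and a limma adjusted p of 1.00 over all genes. Reads from exons outside a deleted part would still be counted, and the labels do not give the floxed exon. Without wild type 2 and wild type 4, which held intestinal RNA, the log2 change was -0.92 ± 0.44 (SE).

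Slc2a2, Tm4sf4 and Mlxipl were far lower in Hnf1a flox islets. Slc2a2 (ENSMUSG00000027690, chromosome 3, 28697903 to 28731359), which encodes the glucose transporter GLUT2, fell from 101.6 ± 87.7 TPM in wild type (SD, n = 7) to 2.16 ± 1.79 TPM in Hnf1a flox (SD, n = 4), or 2.12% of the wild-type mean. Tm4sf4 (ENSMUSG00000027801, chromosome 3, 57425314 to 57441677), a tetraspanin-like membrane protein gene, fell from 195.3 ± 125.9 to 11.1 ± 7.58 TPM. Mlxipl (ENSMUSG00000005373, chromosome 5, 135089890 to 135138382), which encodes the glucose-responsive factor ChREBP, fell from 27.4 ± 16.4 to 2.92 ± 2.47 TPM. In these 3 genes every Hnf1a flox library lay below every wild-type library, which the rule for genes with the largest fall required. Of all genes tested, 68 (0.453%) had no overlap between groups, 67 lower and 1 higher, where chance would give 0.606%. The limma log2 changes were -4.78 ± 0.62, -3.97 ± 0.58 and -2.90 ± 0.53 (SE), with adjusted p of 0.00193, 0.00539 and 0.0493. Wild type 4, which held intestinal RNA, had the highest Slc2a2 (261 TPM) and Tm4sf4 (390 TPM). Without wild type 2 and wild type 4 the wild-type means were 86.9 TPM for Slc2a2, 179.5 TPM for Tm4sf4 and 28.7 TPM for Mlxipl.

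The other 4 genes past the threshold were also lower. Ttr, the transthyretin gene (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), had a log2 change of -3.69 ± 0.65 (SE) and Cltrn, the collectrin gene (ENSMUSG00000015401, chromosome X, 164088830 to 164118860), of -3.86 ± 0.71. Outside the rule for named genes were Defb1, a beta-defensin gene (ENSMUSG00000044748, chromosome 8, 21776599 to 21795185), at -3.94 ± 0.69, and Ppp1r1a, a protein phosphatase inhibitor gene (ENSMUSG00000022490, chromosome 15, 103530279 to 103538003), at -4.13 ± 0.77. Their limma adjusted p were 0.0407 for Ttr and Defb1 and 0.0493 for Cltrn and Ppp1r1a. In wild type 2 these 4 genes lay within the range of the Hnf1a flox libraries, with Ppp1r1a at 3.02 TPM against 3.92 ± 3.05 TPM in Hnf1a flox. In all, 7 of 15011 genes passed the threshold, 0 higher and 7 lower, and 484 had an unadjusted p under 0.05, 49 higher and 435 lower. With library quality weights 43 genes were higher and 73 lower. No gene passed without Hnf1a flox 3, with the pan-endocrine score as a covariate, or with median-of-ratios scaling, while 44 passed without wild type 2 and wild type 4. With that covariate the 7 genes stayed lower, with log2 changes of -3.91 ± 0.75 for Slc2a2, -3.14 ± 0.62 for Tm4sf4, -2.003 ± 0.518 for Mlxipl, -2.70 ± 0.73 for Ttr, -2.49 ± 0.77 for Cltrn, -3.08 ± 0.92 for Defb1 and -3.27 ± 1.06 for Ppp1r1a (SE), all smaller than before and 6 of them with a larger SE.

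**Figure D2:**
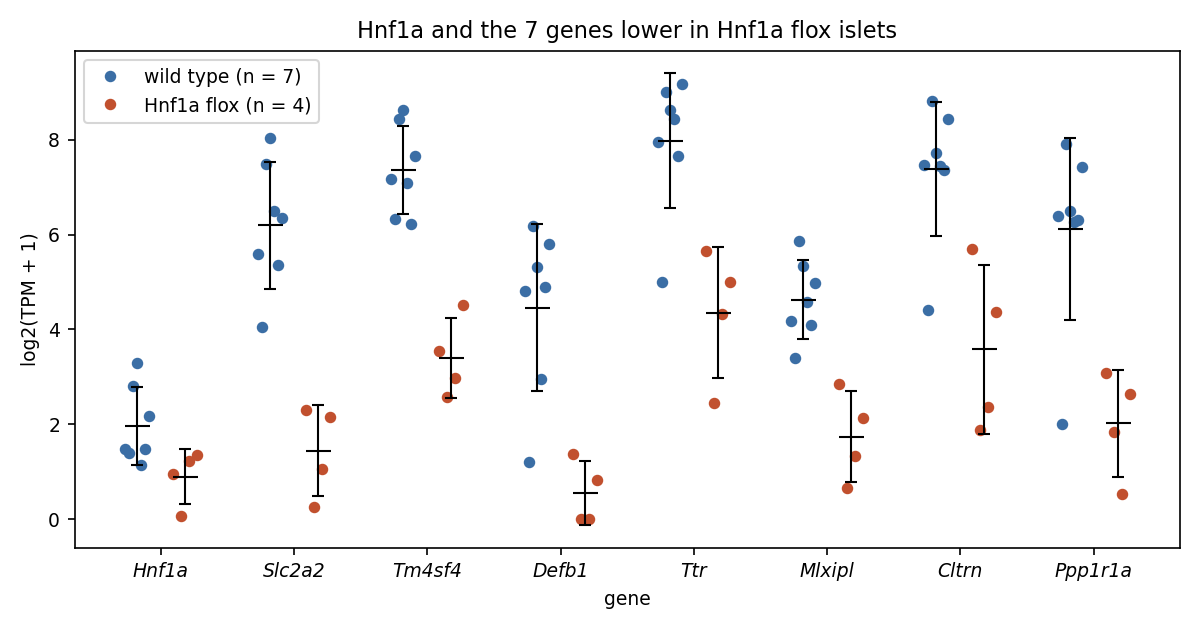
log2(TPM + 1) (y axis) of Hnf1a and the 7 genes past the threshold (x axis), 1 point per library, with bars for the mean and SD of 7 wild-type and 4 Hnf1a flox libraries. Slc2a2 stands at 101.6 TPM on average in wild type and 2.16 TPM in Hnf1a flox, with no overlap, while 1 wild-type library (wild type 2) lies among the Hnf1a flox libraries for Ttr, Cltrn, Defb1 and Ppp1r1a.

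Most genes known to depend on HNF1A in islet, liver and kidney had lower values in Hnf1a flox, 21 of 23, and 2 had higher ones (Igf1 at 0.47 ± 0.50 and Fxyd2 at 0.90 ± 0.55 log2 units, SE, outside the rule for named genes). Of 23 measured genes of this list, 4 were lower over all genes tested (Slc2a2, Tm4sf4, Cltrn and Ttr) and 16 were lower adjusted over the list alone, and none passed as higher. The median log2 change was -2.24, and the list score was 4.22 ± 0.76 in wild type (SD, n = 7) and 2.12 ± 0.53 in Hnf1a flox (SD, n = 4; exact permutation p = 0.00303, the smallest these libraries allow). That permutation p was not adjusted over the gene lists. The exact permutation p was also under 0.05 for alpha cell identity (0.00606), beta cell identity (0.0273) and HNF and FOXA factors (0.0333). For the other lists it was above 0.05. Most genes were also lower for beta cell identity (33 of 34) and oxidative phosphorylation (32 of 32), and higher for leukocytes (26 of 29). For the HNF1A-dependent list the camera adjusted p was 1.26e-38 at the preset correlation, and 0.00749 with an estimated correlation. The pan-endocrine score was also lower on average in Hnf1a flox (7.62 against 9.03), and the list score minus that score differed by -0.70 (pooled SD 0.91, exact permutation p = 0.255). With that score as a covariate the list's median log2 change was -1.96 (adjusted p = 0.00705 with an estimated correlation). Vil1, Ace2, Pklr and Hnf4a of this list are also genes of intestinal epithelium, which wild type 2 and wild type 4 held. Without those libraries the median log2 change was -1.40 over 21 genes, 8 were lower over all genes, and the adjusted p was 0.0117 with an estimated correlation. It was the 1 list that passed this test there. Some other splits of those 9 libraries also called lists by the same test, up to 3, so chance is not excluded for that count.

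**Figure D3:**
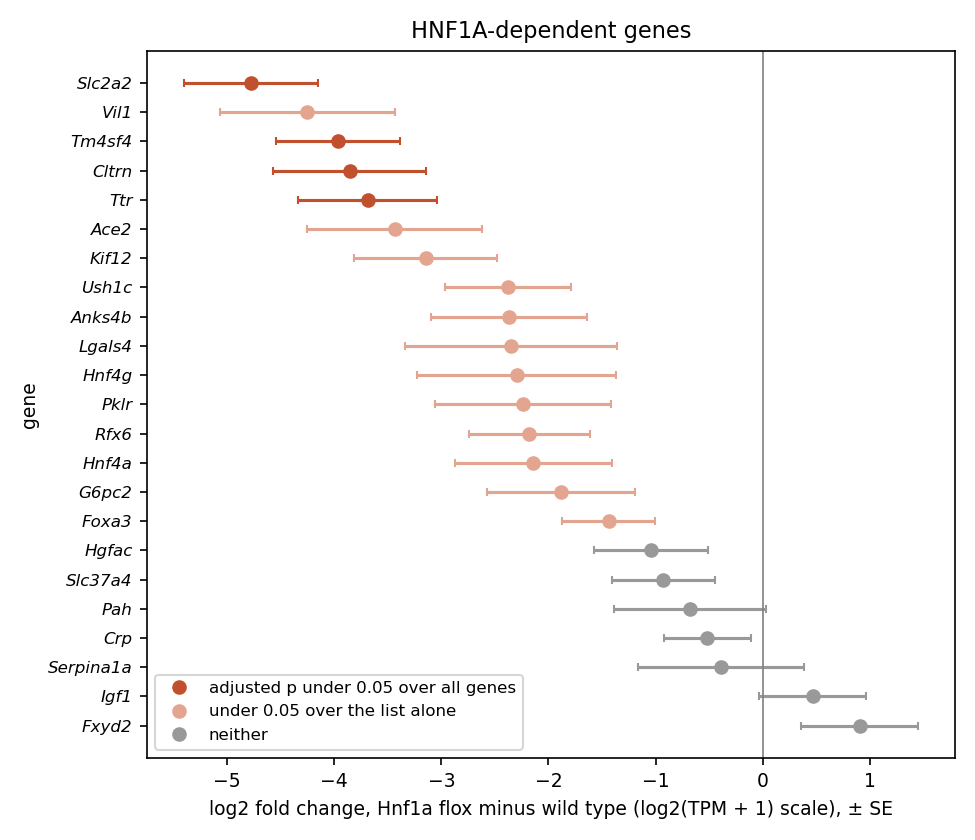
log2 fold change of Hnf1a flox against wild type (x axis, bars SE from limma, n = 4 and 7) for each of the 23 measured HNF1A-dependent genes (y axis), coloured by the adjusted p. 16 genes were lower adjusted over the list alone, among which 4 passed over all genes.

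Genes of beta cell identity had lower values on average. Of 34 measured genes, 1 (Slc2a2) passed over all genes and 15 adjusted over the list alone, all lower. The median log2 change was -1.47, with Ins1 at 27632 ± 12855 TPM in wild type (SD, n = 7) and 11475 ± 11343 TPM in Hnf1a flox (SD, n = 4), and Ins2 at 50411 ± 24972 and 22888 ± 21025 TPM, neither past the threshold. The list passed camera at the preset correlation, with an adjusted p of 6.34e-38, but not with an estimated correlation (adjusted p = 0.172). With the pan-endocrine score as a covariate its median log2 change was -0.20, where the median of all genes was 0.34. Of 21 genes of alpha cell identity, 2 (Cltrn and Ttr) were lower over all genes and 3 adjusted over the list alone (median log2 change -0.78, adjusted p = 0.18 with an estimated correlation). The list of delta cell genes had a median of -0.78 over 13 genes (Sst -1.38 ± 0.80 and Rbp4 -0.82 ± 0.61, SE), and that of PP and epsilon cell genes -0.35 over 10 genes (Ppy -1.57 ± 0.82 and Pyy -0.84 ± 0.77). Their adjusted p with an estimated correlation were 0.354 and 0.581.

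The 4 islet hormones took smaller average shares of the Hnf1a flox libraries, and whether a difference passed adjustment over the 4 tests depended on the scale: none did on shares, and Gcg did on their log2 values. Insulin transcripts were 7.80% ± 3.76 of summed TPM in wild type (SD, n = 7) and 3.44% ± 3.23 in Hnf1a flox (SD, n = 4; exact permutation p = 0.0879, adjusted 0.145). The glucagon gene Gcg was at 1.01% ± 0.49 and 0.314% ± 0.268 (exact permutation p = 0.0364, adjusted 0.145). Sst was at 0.539% ± 0.223 and 0.279% ± 0.240 (exact permutation p = 0.115), and Ppy at 0.342% ± 0.185 and 0.164% ± 0.165 (exact permutation p = 0.145), both with an adjusted p of 0.145. On log2 shares, an alternative added after the data were seen, the exact permutation p was 0.0364 for insulin (adjusted 0.0636), 0.00909 for Gcg (adjusted 0.0364), 0.0545 for Sst and 0.0636 for Ppy (both adjusted 0.0636). Hnf1a flox 2 and Hnf1a flox 3, which also had the lowest pan-endocrine scores, lay below all wild-type libraries for insulin. Hnf1a flox 1 (7.42%) and Hnf1a flox 4 (4.67%) lay within the wild-type range.

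**Figure D4:**
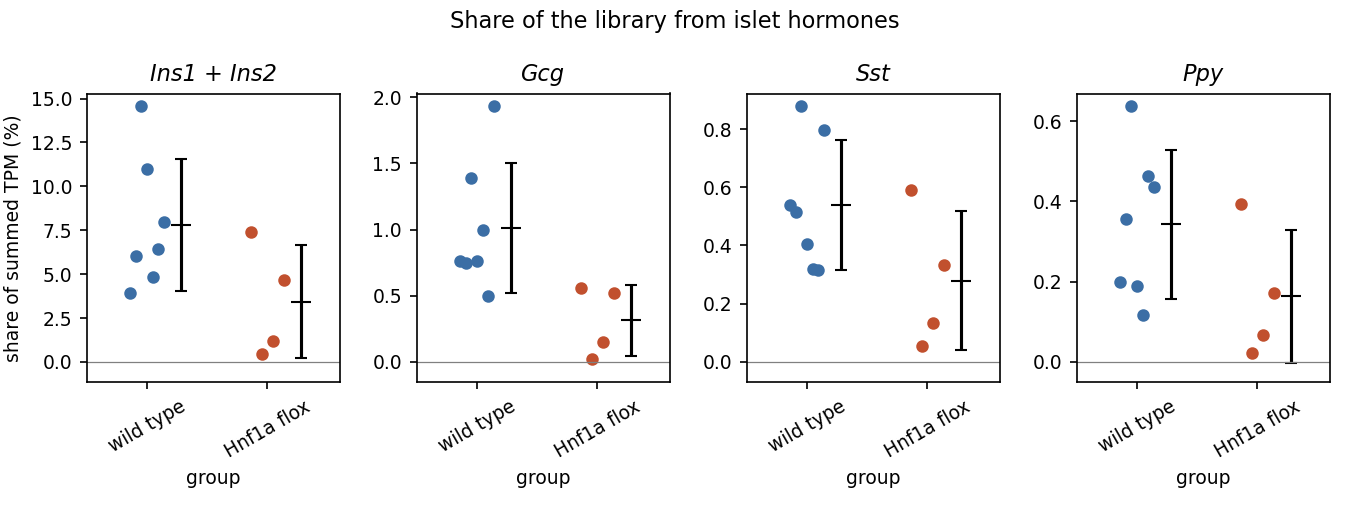
Share of summed TPM, in percent (y axis), from insulin, glucagon, somatostatin and pancreatic polypeptide genes in 7 wild-type and 4 Hnf1a flox libraries (x axis), 1 point per library, with bars for the mean and SD. The insulin share averaged 7.80% in wild type and 3.44% in Hnf1a flox, and 2 of the 4 Hnf1a flox libraries lay within the wild-type range.

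Of the lists for transcription factors, metabolism and secretion, none passed with an estimated correlation. HNF and FOXA factors had a median log2 change of -0.98 over 12 genes (adjusted p = 0.172 with an estimated correlation), with Foxa2 at 24.6 ± 13.9 TPM in wild type (SD, n = 7) and 13.3 ± 9.87 TPM in Hnf1a flox (SD, n = 4). Insulin secretion and exocytosis genes had a median of -0.72 over 45 genes (adjusted p = 0.429 with an estimated correlation), with the granule protein gene Chga at 2478 ± 1554 and 724 ± 587 TPM. Among 32 genes of glycolysis and gluconeogenesis, 1 (Slc2a2) passed over all genes and the median was -0.12, with G6pc2, an islet glucose-6-phosphatase gene, at 596 ± 334 and 219.5 ± 190.6 TPM. The mean of this list was -0.53 (adjusted p = 0.771 with an estimated correlation). Of 24 genes of lipid and cholesterol synthesis 1 (Mlxipl) passed, and the median was -0.05 (adjusted p = 0.962 with an estimated correlation). The TCA cycle (median -0.27), oxidative phosphorylation (-0.26), fatty acid oxidation (-0.24), endoplasmic reticulum stress (-0.20) and endocrine progenitor (-0.55) lists passed at the preset correlation with 0 members past the threshold over all genes. Their adjusted p with an estimated correlation lay at or above 0.581. The camera direction of the TCA cycle and oxidative phosphorylation lists turned without wild type 2 and wild type 4, and that of the secretion list without wild type 5, Hnf1a flox 2 and Hnf1a flox 3. Txnip, a gene induced by high glucose, was at 292 ± 124 TPM in wild type and 325 ± 165 TPM in the hyperglycaemic Hnf1a flox mice.

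Markers of other pancreatic cells showed no list past the threshold with an estimated correlation. Duct genes had a median log2 change of -0.67 over 22 genes (adjusted p = 0.18 with an estimated correlation). Leukocyte genes (median 0.50 over 29 genes) and cell cycle genes (median 0.41 over 32 genes) had higher values and passed at the preset correlation only, with adjusted p of 0.902 and 0.911 with an estimated correlation. Acinar genes had a median of 0.09 over 31 genes (adjusted p = 0.369 at the preset correlation). Lists that passed under neither correlation were oxidative stress (median -0.21), interferon and inflammation (0.24), immediate early genes (-0.02), apoptosis and p53 (-0.004), beta cell disallowed genes (-0.02), endothelial (0.01), stellate (-0.09), Schwann (0.22), erythroid (0.16) and adipocyte (-0.22) cells, and mitochondrially encoded genes (-0.18). In all 16 of 29 lists passed at the preset correlation, 14 lower and 2 higher, and 1 with an estimated correlation, the HNF1A-dependent genes. At the preset correlation other splits of the libraries called a median of 15 lists.

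The interaction of genotype and labelled sex passed for 1 gene by limma (Gm49354, an unnamed model outside the rule), at -8.35 ± 0.91 log2 units, male minus female (SE; limma adjusted p = 3.73e-05), and 413 genes had an unadjusted p under 0.05. The male Hnf1a flox arm is 1 library, with Gm49354 at 0, which is assumed to vary like the others, and with wild type 5 taken as male 0 genes passed by limma (522 at an unadjusted p under 0.05), so no difference between sexes is established.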

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

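The tests in this part were chosen after the data were seen, apart from the statement on glycaemia, and that of Hnf1a without the libraries that held intestinal RNA was chosen once those libraries were known. Islet content was tested in several ways one after another, and all are given.

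In 17 of 186 groups of values checked, a single library stood far from the rest of its group, where chance would give about 1 in 20. Wild type 5 stood apart in the acinar genes Ctrb1 (67425 TPM) and Prss2 (66427 TPM) and in Tff2 (2063 TPM), and it was low in Atp5a1 (113.8 TPM) and Acadl (23.8 TPM). Its scores were low for glycolysis (3.49), the TCA cycle (4.04), oxidative phosphorylation (5.04), fatty acid oxidation (3.02), oxidative stress (4.25) and apoptosis (3.02). Wild type 4 was high in Hnf4g (192 TPM), Mdh1 (522 TPM) and the score of HNF and FOXA factors (4.02), and wild type 3 was high in Scg2 (4811 TPM). Hnf1a flox 4 was high in Hnf4g for its group (0.83 TPM), and Hnf1a flox 3 was low in the score of endoplasmic reticulum stress (4.93). The interaction test gave -8.35 log2 units for Gm49354, which rests on 1 male Hnf1a flox library at 0 TPM, and no gene passed it by limma with wild type 5 taken as male.

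The 7 genes lower in Hnf1a flox could reflect fewer islet cells in those libraries, intestinal RNA in wild type, or chance. Islet content stays open as the whole cause. Relative to the pan-endocrine score the mean log2 value of the 7 genes differed by -2.46 (pooled SD 0.99, exact permutation p = 0.0121), but the same contrast chose these genes. In that mean without the score subtracted, the higher of Hnf1a flox 1 and Hnf1a flox 4 lay 0.27 below the lowest wild-type library, wild type 2. It lay 2.49 below the next. The yardstick was the wild-type SD of the pan-endocrine score, 0.67, not the SD of that mean. The list of HNF1A-dependent genes, fixed beforehand, differed by -0.70 on this measure (pooled SD 0.91, exact permutation p = 0.255), with 2 of the 4 Hnf1a flox libraries below all wild-type ones. It passed camera with an estimated correlation in the fit with the pan-endocrine score as a covariate (median log2 change -1.96, adjusted p = 0.00705). Both tests thus pointed lower and only 1 passed. The subtraction takes the list to follow the pan-endocrine score in full, which was not tested. Whether the genotype itself lowers that score was not tested either. Without wild type 2 and wild type 4 the median log2 change of the 7 genes was -4.30 against -3.94 with them, which argues against intestinal RNA, and 4 of 100 splits of the 11 libraries called at least 7 genes, the real one included, though the highest other split called 8489, which points to a structure of the samples. Hyperglycaemia cannot be told apart from genotype, since 0 libraries combine the other way.

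Intestinal epithelium genes scored 5.49 in wild type 2 and 8.59 in wild type 4, where the other 9 libraries had at most 0.23, and in wild type 2 many genes lower in Hnf1a flox were low as well. The gene set tested was the 38 genes lower in Hnf1a flox without wild type 2 and wild type 4, so wild type 2 had no part in choosing it, and on a scale from 0 (Hnf1a flox mean) to 1 (mean of the 5 other wild-type libraries) its median position was 0.17 over the 26 genes with no sign of an intestinal source, against 0.91 for wild type 4. Dilution by other RNA is argued against by its insulin share of 6.01%, above the lowest other wild-type library at 3.92%. A wrong genotype label may account for the position but stays open. Over all 38 genes the position was 0.32, a value that depends on intestinal expression of these genes (subtracting a share of wild type 4 gave -0.02, which also removes islet RNA). Wild type 2 lay at or below the highest Hnf1a flox library in 20 of the 26 genes. It lay above that library in 6, including Mlxipl (9.53 against 6.18 TPM) and Ifi202b (38.9 against 0 TPM). Wild type 3 was also at 0 TPM for Ifi202b, so this gene does not follow the genotype label. Wild type 2 also lay above in 12 genes with a sign of an intestinal source, including Slc2a2 (15.6 against 3.90 TPM) and Tm4sf4 (79.6 against 21.9 TPM). Hnf1a was at 1.62 against 1.55 TPM, or 128 reads in wild type 2 against 129 in Hnf1a flox 4, which does not decide. Wild type 2 is labelled as normoglycaemic, but that label has the same split as the genotype label in question. For Hnf1a itself, the change without wild type 2 and wild type 4 was -0.92 ± 0.44 (SE), which does not decide whether their intestinal RNA made the difference.

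Ddx3y was at 21.3 TPM in wild type 5, labelled female, against at most 0.03 TPM in the other libraries labelled female. Xist relative to Ddx3x was 0.10% of the lowest other library labelled female, which argues against a female library with RNA of a male mixed in. The summed Y-linked genes relative to Ddx3x were 0.55, between 0.49 and 0.66 in the libraries labelled male, so a single wrong sex label is a candidate explanation. No biological explanation was tested.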

How the results depend on the processing

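The alternatives with covariates for islet, leukocyte or islet and acinar content, voom, log2 shares, wild type 5 as male, and those without several libraries were added after the data were seen. The count of 7 genes was 12 with a filter of 5 TPM, 4 in females only (which keeps wild type 5), 28 in females without wild type 5 (6 higher, 22 lower), 8 without wild type 5 or with it as male in the sex term, 116 with library quality weights (43 higher, 73 lower), and 2 with no sex term, no mean-variance trend, or the acinar or leukocyte score as a covariate. It was 0 with no filter on low values, median-of-ratios scaling, quantile normalization, voom on recovered reads, the pan-endocrine score as a covariate alone or with the acinar score, without wild type 4, wild type 5 and Hnf1a flox 3, and without wild type 5, Hnf1a flox 2 and Hnf1a flox 3. In these fits with 0 genes by limma, 176 to 854 genes had an unadjusted p under 0.05. The cause was not tested. Leaving out 1 library gave 0 (without Hnf1a flox 3) to 23 genes (without wild type 6), with 15 without wild type 1, 14 without wild type 2, 17 without wild type 4, 12 without wild type 7, and 2 without Hnf1a flox 2 or Hnf1a flox 4. Without wild type 2 and wild type 4 it was 44, of which 38 were lower, and all 7 genes were shared. 12 of 100 splits of those 9 libraries called at least as many genes, the highest other 11527, so chance is not excluded for that count. Over 33 alternatives no fold of the 7 genes reversed, but each lost its call in some: Slc2a2 (from -5.63 to -3.56) kept it in 24, Tm4sf4 in 22, Ttr in 17, Defb1 in 16, Mlxipl in 15, and Cltrn and Ppp1r1a in 14. With the pan-endocrine covariate, which moved the median of all genes to 0.34, Slc2a2 was at -3.91 ± 0.75 (SE). The median of all genes also moved to -0.14 with the leukocyte score and 0.21 with the endocrine and acinar scores. The replicate block gave 100 genes (7 higher, 93 lower), but the numbers do not pair the libraries, since same-numbered libraries deviated with correlations of 0.01, 0.33, -0.07 and 0.17. Of 16 lists, 1 passed with an estimated correlation, by fry, and with an estimated correlation without wild type 2 and wild type 4 or with the pan-endocrine covariate, and 9 passed without wild type 4, wild type 5 and Hnf1a flox 3. 46 of 100 splits called at least 16 lists at the preset correlation, the highest other 20, so chance is not excluded for that count. The camera direction reversed without wild type 2 and wild type 4 for the TCA cycle (median -0.151) and oxidative phosphorylation (-0.0913), the latter also with library quality weights (0.0802) and without wild type 4 alone, with leave-one-out medians from -0.52 to 0.11. It reversed for insulin secretion without wild type 5, Hnf1a flox 2 and Hnf1a flox 3 (0.15). The insulin share, as log2, differed by -1.78 (exact p = 0.0364). In females only the insulin and Sst share differences were smaller than with all libraries, and neither passed. The Gcg share difference was -0.58 percentage points in females only, with or without wild type 5, and -0.78 to -0.55 leaving out 1 library. Its exact p reached 0.05 or more without any one Hnf1a flox library. The Ppy share difference was -0.07 in females only, and -0.26 (without Hnf1a flox 1, past the threshold) to -0.13 leaving out 1 library. The genes past the interaction test were 244 with no filter, 2 with a filter of 5 TPM, 3 without wild type 5 and 0 by limma with it as male (522 at an unadjusted p under 0.05). DESeq2 was not run.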

Other observations

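The hypotheses here were formed after the values were seen, except for the test of genes near Hnf1a. Without wild type 2 and wild type 4, the lower genes, all outside the rule for named genes, included Kif12 (log2 change -3.74 ± 0.58, SE), Gc (-3.55 ± 0.57), Rfx6, an islet transcription factor gene (-2.45 ± 0.57), Casr (-2.06 ± 0.52), Trpm5 (-2.09 ± 0.51) and Pcsk9 (-2.20 ± 0.43), and the higher ones included Pagr1a (2.24 ± 0.45) and Hamp (2.15 ± 0.46). As 12 of 100 splits of those 9 libraries called as many genes, this set is a description.

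Slc2a2 relative to insulin was lower in 4 of 4 Hnf1a flox libraries than in any wild-type library, at -13.94 ± 0.43 log2 units (SD, n = 4) against -9.96 ± 1.06 (SD, n = 7; exact permutation p = 0.00303, the smallest possible, adjusted 0.0182 over 6 ratios). The same contrast had already called Slc2a2, so this p is no separate evidence. Among the hormones, the lowest adjusted p of 4 ratios was 0.286, and both Hnf1a flox libraries with a pan-endocrine score in the wild-type range had insulin shares in that range, so the lower hormone shares may reflect fewer islet cells in the other libraries, which stays open, since the ratio of Pyy to Gcg was higher in Hnf1a flox by 1.54 log2 units (exact permutation p = 0.0273, adjusted 0.0818), with 4 of 4 libraries above the wild-type median. The ratio of Ppy to Gcg was higher by 0.82 log2 units in Hnf1a flox, but with an exact permutation p of 0.173 (adjusted 0.286) the hypothesis that PP hormone rises relative to glucagon was left open.

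Strain variants carried with the floxed allele could change genes near Hnf1a. Of 247 genes within 10 Mb, 2 had an unadjusted p under 0.05, or 0.81%, against 3.26% elsewhere (Fisher's exact test, two-sided, p = 0.0269). Low p-values were thus not more frequent near Hnf1a. A variant that changes only a few linked genes need not raise this share, so the test does not exclude the hypothesis. Mlxipl, also on chromosome 5, lies outside that window and was not covered.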
